A study of Mus musculus with 9 samples.

How the data were processed

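Per the labels' protocols, bone marrow stromal cells were taken from the leg bones of mice that carry the irtTA-GBD*-TAg transgene, immortalised conditionally with dexamethasone and doxycycline, cloned, and kept without either drug for 3 days before RNA was taken. Adipogenic progenitors received 10 ng/ml IFNγ for 3 days. Poly(A) RNA was made into libraries with a directional kit, and the pooled libraries were spread over all lanes of a HiSeq sequencer for single reads, so no lane batch separates the groups. The values analysed are the deposited read counts per Ensembl gene, whole numbers that were not normalized, 1 column per library. The submitters' processing notes name CASAVA 1.8.0, bedtools 2.11 and the mouse build mm9. The aligner, the counting tool and its strand setting, and any filter are not given in the sources used here. Reads of near-identical family members and of overlapping or antisense genes therefore cannot be assigned with certainty. The deposited table also gives the number of exons and the exonic length per gene, of which the length was used in a check of length bias.

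Groups were read from the titles and the series design, which names 3 biological replicates of each kind. Whether these are separate clones, cultures or animals is not given, so p values measure only the spread between these samples. No library pair within a group agreed within sampling noise. Totals ran from 27440089 to 39251602 counts, so that a count of 0 allowed up to 0.0764 to 0.109 CPM, taken as 3 counts per library. Such floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. All 24186 genes of the table were read, of which 104 names belonged to several identifiers. Gene lists then took the identifier with the most counts.

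Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group, which left 15098, and libraries were scaled with TMM. A quasi-likelihood model with robust estimation and a term for the group was fitted to all 9 libraries. All groups thus shared 1 estimate of spread per gene, although their spread was unequal. Pairs of osteogenic libraries correlated in log2 CPM at 0.967 to 0.973. Untreated adipogenic pairs correlated at 0.943 to 0.951 and treated ones at 0.941 to 0.960. The shared estimate may therefore be too low for IFNγ against untreated, which was not tested apart from the number of libraries. The 3 pairs of groups were compared with two-sided F tests and Benjamini-Hochberg adjustment, at 0.05. The SE of a log2 fold change was taken as its size over the square root of F. CPM were computed from the deposited counts and the TMM-scaled library sizes. The biological coefficient of variation was 0.378. An exact permutation test of 3 libraries against 3 cannot give a two-sided p below 0.1.

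The 33 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. For each main comparison the rule took the 5 largest rises and the 5 largest falls among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups, leaving out predicted genes. It also took up to 4 members of each list with the smallest adjusted p and a mean of at least 1 CPM in the higher group, and always Ifngr1, Ifngr2, Irf1, Cxcl12, Pparg, Cebpa, Dlk1, Runx2, Sp7, Alpl and Col1a1. Results for some other genes that the rule takes are not reported here. Chance gives 10% of unchanged genes no overlap between 3 libraries and 3. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 33 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry is not printed for each list and differed in both directions. In osteogenic against adipogenic progenitors fry passed the GTPases (adjusted p = 0.00703) and MHC class I (0.00696), which the estimated correlation did not. It also passed the endothelial list (0.0232), which camera did not. It did not pass the cholesterol list there (0.124) nor the S and G2/M genes with IFNγ (0.0536), both past the preset camera. Symbols were matched to the file by name or, for renamed genes, by Ensembl identifier through GENCODE M21. The list entries Il10, Cd86, C1rb, C1qa, C1qb, C1qc, Lep, Pck1, Ankh, Ucma, Hmgcs1, Hoxb1, Hoxd1, Hoxd12, Rian, Mirg, Snurf, Kcnq1ot1, Adgre1, Tyrobp, Cd3e, Hbb-b1 and Cldn5 had no match and were not analysed here.

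The numbers 4, 5 and 6 in the titles were checked as a pairing before calls were compared. Deviations from the group means correlated across genes at 0.778, 0.769 and 0.779 for treated and untreated adipogenic libraries of the same number. For those of different numbers the values were −0.461 to −0.279. Deviations of 3 libraries sum to 0 within a group, so these negative values largely follow from the positive ones and add no separate evidence. Osteogenic libraries showed no such pairing with either group (−0.0546 to 0.0552 for the same number). Same-numbered adipogenic libraries are therefore called a line here, a name drawn from the data and not from the labels. A fit with the line as a replicate block of the adipogenic libraries was added after this check. Its biological coefficient of variation was 0.228.

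Alternatives were DESeq2 size factors and upper-quartile scaling in the edgeR fit, the DESeq2 1.42.0 Wald test, limma-voom, no filter beyond 1 count, a filter of 5 CPM in 3 libraries, only the 6 libraries compared, replicate blocks, a fold minimum of 2 with glmTreat, and each library left out in turn. Fits were tested on simulated counts with about 200 changed genes. For IFNγ against untreated, 14917 genes were run, 9.09, 59.4 and 77.8% of genes changed by a log2 fold of 1, 2 and 3 were recovered, and 4.95% of calls were false. With simulated lines and the block, on 14974 genes, these shares were 39.3, 73.1 and 93.2%, with 7.28% of calls false. For osteogenic against adipogenic, on 14879 genes, they were 14.3, 59.4 and 82.5%, with 4.85% false. In the list test a raised list had an adjusted p of 1.11e-35 and 0 of 20 unchanged lists were called by camera. Its genes were drawn independently, so it cannot show how often camera falsely calls lists whose members vary together. Estimated correlations with IFNγ were 0.459 for the antiviral genes and 0.672 for the S and G2/M genes.

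The chromosome of each gene was looked up by Ensembl identifier in GENCODE M21 on GRCm38, which held 14545 of the 15098 genes (96.3%). No coordinates are printed, because the table holds none and this annotation is on another build than mm9. Deviations by chromosome are log2 CPM minus the mean of the other 2 libraries of the group, over genes with a mean of at least 1 CPM. Intervals of count ratios are exact Clopper-Pearson intervals from SciPy 1.17.1 under Python 3.11.15, and figures were drawn with matplotlib 3.10.9.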

Results

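Poly(A) RNA was sequenced from bone marrow stromal cells of adult C57Bl/6 mice. The cells carried a transgene from which dexamethasone and doxycycline induce large T antigen, so that they grew as conditionally immortalised cultures from which clones were taken. Both inducers were left out for 3 days before RNA was prepared. The 9 libraries formed 3 groups of 3. One group held progenitors with adipogenic potential, the next held such progenitors given 10 ng/ml interferon-γ (IFNγ) for 3 days, and the last held progenitors with osteogenic potential. The libraries are named here by their group and by the number in their label, 4, 5 or 6.

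The deposited counts summed to 34686951, 34786398 and 38074320 in untreated adipogenic replicates 4, 5 and 6. They summed to 32834051, 34627140 and 35268721 in the treated libraries and to 33295238, 27440089 and 39251602 in the osteogenic ones. A count of 0 in a library allowed up to 0.0764 to 0.109 CPM, the counts scaled to library size. The 10 genes with the most counts took 4.12 to 6.23% of an adipogenic library, treated or not, and 10.7 to 13.3% of an osteogenic one, where Col1a1 alone took 2.80 to 3.93%. Transcripts of the mitochondrial genome made up 0.930 to 1.38% of the untreated adipogenic libraries, 0.660 to 0.706% of the treated ones and 0.945 to 1.06% of the osteogenic ones. Values below are mean CPM ± SD over 3 libraries per group, log2 fold changes carry their SE, and adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. A value alone in parentheses after a gene or list is its adjusted p.

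The first comparison asked what IFNγ changed in adipogenic progenitors. Genes of the interferon response and of antigen presentation rose, some of them from near absence. Gbp4 (ENSMUSG00000079363), an interferon-inducible GTPase, went from 0.879 ± 0.209 to 1067 ± 247 CPM, a log2 fold change of 10.24 ± 0.33 (adjusted p = 8.66e-06). Ciita (ENSMUSG00000022504), the transactivator of MHC class II genes, went from 0.205 ± 0.135 to 138 ± 2.95 CPM (adjusted p = 7.78e-05). H2-Aa (ENSMUSG00000036594), an MHC class II chain, went from 0.122 ± 0.102 to 137 ± 50.9 CPM (adjusted p = 0.000204). The other members of the 5 largest rises were Gbp8 (ENSMUSG00000034438), from 0.0567 ± 0.0569 to 81.2 ± 6.82 CPM, and Gbp10 (ENSMUSG00000054588), from 0.237 ± 0.0681 to 252 ± 86.4 CPM. The untreated levels behind such folds were a few counts, 6 for Gbp8, 13 for H2-Aa, 22 for Ciita and 26 for Gbp10 over the 3 libraries. The ratio of pooled counts for Gbp8 was 1496, with an exact 95% interval of 687 to 4078 that covers counting error only, and that for H2-Aa was 1167 (682 to 2193).

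In all, 341 of 15098 genes tested passed an adjusted p of 0.05. Of these, 304 rose and 37 fell, and 280 had an absolute log2 fold change over 1. The 5 largest falls were in Ltbp2 (ENSMUSG00000002020), which codes for a protein of matrix microfibrils, Fos (ENSMUSG00000021250) and Egr1 (ENSMUSG00000038418), both immediate early transcription factors, Scube3 (ENSMUSG00000038677) and Col12a1 (ENSMUSG00000032332). Ltbp2 fell from 40.7 ± 25.9 to 2.14 ± 1.89 CPM (adjusted p = 0.029), Fos from 37.5 ± 8.47 to 3.77 ± 3.8 (0.0447), Egr1 from 399 ± 62.1 to 49.7 ± 31.2 (0.0262), Scube3 from 16.4 ± 1.11 to 1.7 ± 1.04 (0.00381) and Col12a1 from 1112 ± 475 to 194 ± 29.8 (0.0253). Same-numbered treated and untreated libraries deviated together from their group means, and with that pairing as a replicate block 1631 genes passed, 986 up and 645 down, among them 340 of the 341. With 1 library left out the count fell to 211, 221 and 227 without untreated replicates 4, 5 and 6, and to 278, 275 and 194 without the treated ones. The calls for Ltbp2 and Egr1 were lost in 4 of these 6 fits, with adjusted p up to 0.0980 and 0.120, and those for Fos and Col12a1 in 5, with adjusted p up to 0.154 and 0.0959. Ltbp2 lost its call without untreated replicate 4 or 6 or treated replicate 4 or 5. Fos lost its call without untreated replicate 4, 5 or 6 or treated replicate 4 or 6. Egr1 lost its call without untreated replicate 4, 5 or 6 or treated replicate 6. Col12a1 lost its call without untreated replicate 4 or 6 or treated replicate 4, 5 or 6. Ltbp2 (0.0999), Fos (0.144) and Egr1 (0.0882) lost their calls with only the 6 libraries compared. Fos (0.0663) lost its call with no filter beyond 1 count. Fos (0.0632) lost its call with the block over all 9 libraries. The fits with 1 library left out did not pair the lines. With the replicate block of the adipogenic lines, chosen after the data were seen, all 4 passed. Adjusted p there was 0.00217 for Ltbp2, 0.02 for Fos, 0.00918 for Egr1 and 0.0139 for Col12a1.

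Of the 17 genes of IFNγ signalling, 11 rose and Ifngr2 fell. Adjusted over the list alone, 13 rose and 1 fell. Irf1, a transcription factor of the interferon response, went from 53.6 ± 9.73 to 790.5 ± 137 CPM (log2 fold change 3.88 ± 0.21, adjusted p = 9.29e-05). Stat2 went from 149.6 ± 29.5 to 766 ± 76.2 CPM (2.36 ± 0.18, 0.00045) and Batf2 from 0.354 ± 0.216 to 158 ± 44.3 (8.79 ± 0.46, 9.09e-05). AI451557, the name under which the file holds Nlrc5, the transactivator of MHC class I genes, went from 61.8 ± 13.3 to 619.8 ± 165 CPM (adjusted p = 0.00045). Ifngr2, a chain of the IFNγ receptor, fell from 128 ± 19.4 to 64.5 ± 16.9 CPM (−0.99 ± 0.19, 0.0398), a call that was lost in 5 of the 6 fits with 1 library left out (adjusted p up to 0.188). Ifngr1, the other chain, stood at 90.4 ± 42.2 and 61.1 ± 14.2 CPM and did not pass (adjusted p = 0.499). The list was up against all other genes (camera adjusted p = 1.31e-43). Ifngr2 lost its call without untreated replicate 4, 5 or 6 or treated replicate 4 or 6. Ifngr2 (0.15) lost its call with only the 6 libraries compared. Ifngr2 (0.0552) lost its call with no filter beyond 1 count. It passed with the replicate block of the lines (0.00192).

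All 18 interferon-inducible GTPases had a positive fold change, and 15 rose (18 adjusted over the list alone, camera adjusted p = 3.82e-156). Gbp3 went from 42.3 ± 11 to 1001 ± 92.1 CPM (4.57 ± 0.24, 8.38e-05) and Gbp7 from 20.1 ± 6.6 to 481 ± 55.3 (4.58 ± 0.27, 0.000106). Of 22 genes of MHC class I presentation, 16 rose (19 over the list alone, camera adjusted p = 4.16e-65). They included H2-T22, from 64.9 ± 20.2 to 462 ± 59.3 CPM (0.000738), the proteasome activator gene Psme1, from 61.9 ± 8.43 to 299.9 ± 52 (0.000813), and the loading factors Tapbpl, from 17.9 ± 4.16 to 106 ± 20.9 (0.000813), and Tapbp, from 297 ± 58.9 to 1318 ± 60.4 (0.000898). Of 12 tested MHC class II genes, 8 rose (10 over the list alone, camera adjusted p = 1.19e-54). H2-Ab1 went from 0.493 ± 0.0913 to 144 ± 63.9 CPM (9.37e-05) and H2-DMa, which helps load peptides, from 5 ± 1.61 to 50.8 ± 12.6 (0.00114). Of 33 antiviral interferon-stimulated genes, 23 rose (32 over the list alone, camera adjusted p = 6.55e-75). Dtx3l went from 31.9 ± 4.46 to 262 ± 40.4 CPM (0.000208), its partner Parp9 from 45.5 ± 11.7 to 284 ± 36.2 (0.000595) and Herc6 from 22.1 ± 4.67 to 238 ± 56 (0.000615). The Gbp, H2, Irg, Oas and Ifit families have near-identical members, so the level of a single member is uncertain where reads were shared.

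**Figure D1:**
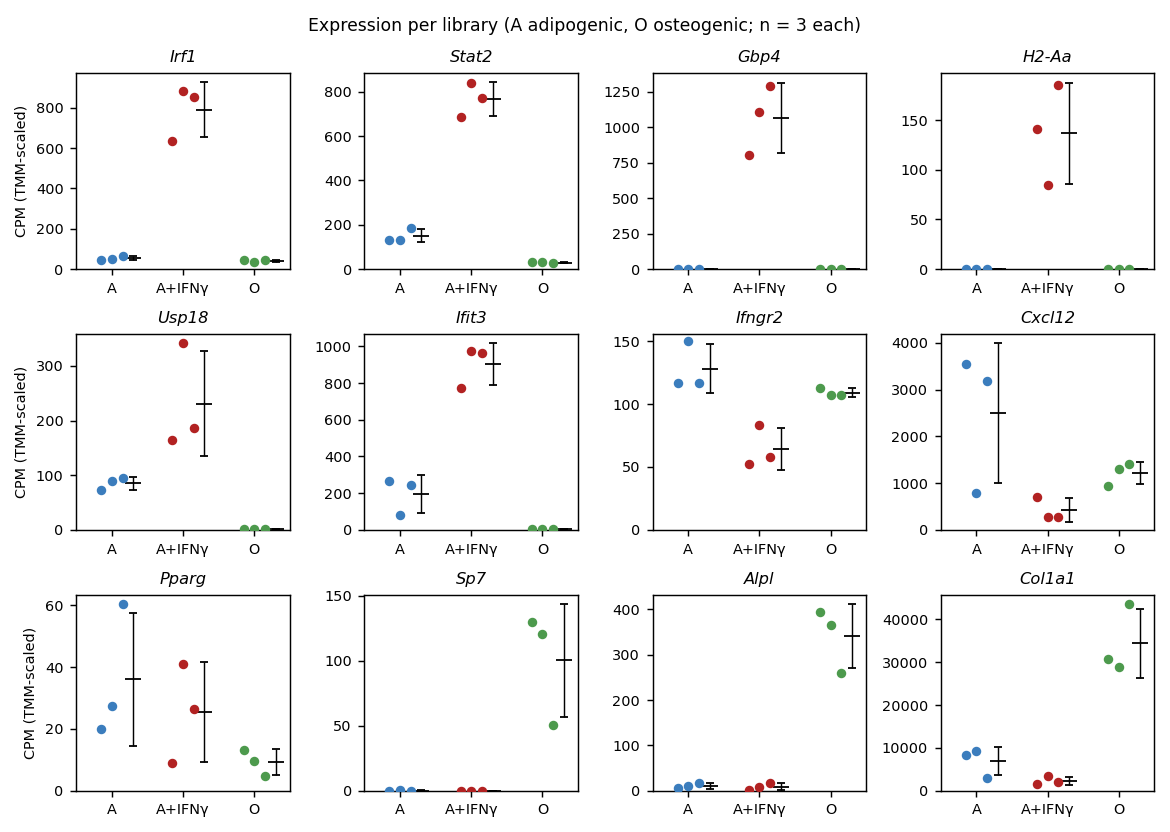
CPM of 12 genes in each of the 9 libraries on linear axes that start at 0, with points for libraries and a bar for the mean ± SD of each group of 3. Irf1, Stat2, Gbp4 and H2-Aa were higher in each treated library than in any other library, while Sp7, Alpl and Col1a1 were higher in each osteogenic library than in any adipogenic one.

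Among 20 tested chemokine and cytokine genes, 4 rose, all of them chemokines (7 up and 1 down over the list alone, 5 up and 1 down with the replicate block, camera adjusted p = 3.21e-05). Cxcl10 went from 9.95 ± 2.76 to 490.3 ± 254 CPM (0.000859), Cxcl9 from 2.49 ± 0.2 to 171 ± 119 (0.00116), Ccl8 from 0.0626 ± 0.03 to 6.85 ± 1.78 (0.00177) and Cxcl11 from 0.164 ± 0.161 to 12.9 ± 11.8 (0.0251). The Cxcl11 call was lost in 4 of the 6 fits with 1 library left out, with adjusted p up to 0.105. Cxcl12, a chemokine that holds blood stem cells in the marrow, stood at 2497 ± 1498 CPM without and 418 ± 254 CPM with IFNγ (log2 fold change −2.58 ± 0.61). It did not pass edgeR's test (adjusted p = 0.0858). It passed with the replicate block (adjusted p = 0.0138), with DESeq2 (0.000154) and without untreated replicate 5 (0.0249). Of 19 immunoregulatory genes, 4 rose (5 over the list alone, 5 up and 1 down with the replicate block, camera adjusted p = 1.62e-05), with a list median of only 0.10. Cd274, which codes for PD-L1, went from 6.24 ± 1.08 to 199.7 ± 22.9 CPM (0.000106), Ido2 from 0.315 ± 0.112 to 16.4 ± 2.95 (0.000283), Tnfsf10 (TRAIL) from 0.231 ± 0.0912 to 22 ± 10.7 (0.00533) and Nos2 from 0.0564 ± 0.0745 to 2.23 ± 1.2 (0.0414). Nos2 lost its call in 5 of the 6 fits with 1 library left out (adjusted p up to 0.154). Of 14 complement genes, 3 rose (4 up and 1 down over the list alone, 3 up and 2 down with the replicate block, camera adjusted p = 4.66e-07), namely C4b, from 1.39 ± 0.724 to 186 ± 9.2 CPM (0.00017), the C1 inhibitor gene Serping1, from 0.515 ± 0.252 to 99.9 ± 1.3 (0.00178), and Cfb, from 0.0981 ± 0.0362 to 2.03 ± 0.397 (0.00562). Of 22 cell death genes, 5 rose (10 over the list alone, 10 up and 1 down with the replicate block, camera adjusted p = 1.10e-07). They included Casp12, from 29.4 ± 5.89 to 171 ± 17 CPM (0.000921), Zbp1, from 7.32 ± 5 to 544 ± 24.9 (0.00204), Xaf1 (0.0168), whose call was lost in 5 of the 6 fits with 1 library left out (adjusted p up to 0.0895), and Mlkl, named after its value was seen. Zbp1 and Xaf1 are also members of the antiviral list. Cxcl11 lost its call without untreated replicate 4 or 5 or treated replicate 5 or 6. Nos2 lost its call without untreated replicate 5 or 6 or treated replicate 4, 5 or 6. Xaf1 lost its call without untreated replicate 4, 5 or 6 or treated replicate 5 or 6. Cxcl11 (0.136) lost its call with limma-voom. Cxcl11 (0.0999) and Nos2 (0.111) lost their calls with only the 6 libraries compared. With the replicate block of the lines, Cxcl11 (0.00055), Nos2 (0.00731) and Xaf1 (0.0138) passed.

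Genes of sugar breakdown also rose. Of 26 glycolysis and hypoxia genes, 7 rose and none fell (18 up over the list alone, 16 up with the replicate block, camera adjusted p = 5.62e-14). Hk2, which codes for a hexokinase, went from 70.6 ± 9.76 to 259 ± 23 CPM (1.88 ± 0.14, 0.00045), Pgk1 from 21.6 ± 3.36 to 45.8 ± 3.3 (1.09 ± 0.14, 0.00623), Ldha from 305 ± 61.3 to 644 ± 98.6 (1.08 ± 0.19, 0.0223) and Tpi1 from 263 ± 11.9 to 547 ± 153 (1.05 ± 0.20, 0.0336). The calls for Ldha and Tpi1 were lost in 4 of the 6 fits with 1 library left out, with adjusted p up to 0.0832 and 0.118. All 42 genes of S and G2/M phase had a positive fold change, with a median of 1.15 on the log2 scale. None passed edgeR's test over all genes, although 30 had an unadjusted p under 0.05, 25 passed over the list alone, 28 passed with the replicate block, 15 passed with DESeq2 and 0 with limma-voom. The list was up by camera (adjusted p = 2.87e-16) but not with an estimated correlation (adjusted p = 0.229). Ccna2, the gene of cyclin A2, stood at 19.5 ± 6.67 and 53.8 ± 17.5 CPM (0.0959, with the block 0.0386, with DESeq2 0.0033) and Tpx2 at 45.5 ± 11.4 and 101 ± 15 (0.101, with the block 0.0337, with DESeq2 0.00578). The 23 cyclin-dependent kinase inhibitors and p53 targets had a median of −0.38 (camera adjusted p = 0.0014, with an estimated correlation adjusted p = 0.320). None of them passed edgeR's test alone, 5 had an unadjusted p under 0.05, all of them lower, DESeq2 called 3, limma-voom 0 and the fit with the replicate block 4. Plk2 stood at 281 ± 77.7 and 139 ± 34.5 CPM (0.104, with the block 0.00582, with DESeq2 0.00664). Ldha lost its call without untreated replicate 4 or 5 or treated replicate 4 or 6. Tpi1 lost its call without untreated replicate 4, 5 or 6 or treated replicate 5. Ldha (0.106) and Tpi1 (0.129) lost their calls with only the 6 libraries compared.

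Matrix genes were lower as groups. Of 39 genes of the fibroblast matrix, 1, Col12a1, fell over all genes (11 over the list alone, 12 with the replicate block, camera adjusted p = 6.57e-09). Of 28 osteoblast and bone matrix genes, 1, the Wnt inhibitor gene Wif1, fell from 3.33 ± 1.51 to 0.563 ± 0.152 CPM (0.0274; 5 genes over the list alone, 7 with the block, camera adjusted p = 0.000101). The Wif1 call was lost in 5 of the 6 fits with 1 library left out (adjusted p up to 0.129). Col1a1, the gene of the main chain of type I collagen, stood at 6899 ± 3324 and 2262 ± 975 CPM and passed with the block and with DESeq2 but not in the unpaired edgeR fit (0.15, with the block 0.0431, with DESeq2 0.00787), as did Col1a2 at 7210.2 ± 1769 and 3941 ± 392 (0.136, with the block 0.0396, with DESeq2 0.00242). Of 43 BMP and TGF-β genes, 2 fell, Tgfb2 from 62.3 ± 10.3 to 23.8 ± 5.73 CPM (0.0192) and Ltbp2, and with the replicate block 1 rose and 7 fell. That list was down by camera (adjusted p = 0.00267), but not with an estimated correlation (adjusted p = 0.313) nor without treated replicate 4 (0.221). The Tgfb2 call was lost in 3 of the 6 fits with 1 library left out (adjusted p up to 0.0725). Of 42 Wnt genes none passed edgeR's test over all genes. Among them 8 had an unadjusted p under 0.05, 1 of them higher, DESeq2 called 6 lower and limma-voom 0, 3 fell over the list alone, and with the block 2 rose and 7 fell (camera adjusted p = 0.00078, down). Lef1, a transcription factor of this pathway, stood at 2.72 ± 1.6 and 0.362 ± 0.122 CPM (0.0575, with the block 0.0308, with DESeq2 0.000142). All 13 smooth muscle and pericyte markers were lower, with a median of −1.24, and the list was down by camera (adjusted p = 1.62e-05) but not with an estimated correlation (adjusted p = 0.197). None of the 13 passed edgeR's test alone, 4 had an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 1, and 5 passed with the block, among them Myl9 at 336 ± 51 and 147 ± 21.7 CPM (0.0623, with the block 0.034, with DESeq2 0.000534, with limma-voom 0.0363, with upper-quartile scaling 0.0481). Wif1 lost its call without untreated replicate 5 or 6 or treated replicate 4, 5 or 6. Tgfb2 lost its call without untreated replicate 5 or 6 or treated replicate 6. Wif1 (0.0678) lost its call with limma-voom. Wif1 (0.0897) and Tgfb2 (0.0651) lost their calls with only the 6 libraries compared. Wif1 passed with the replicate block of the lines (0.00866).

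The fat and bone regulators Pparg, Cebpa, Runx2, Alpl, Sp7 and Dlk1 did not pass the test with IFNγ, which does not exclude a change. Pparg, the main transcription factor of fat cells, stood at 36 ± 21.6 and 25.4 ± 16 CPM (−0.50 ± 0.62, 0.797) and Cebpa at 30.9 ± 26.5 and 17 ± 7.33 (−0.86 ± 0.60, 0.603). Runx2, a transcription factor of bone-forming cells, stood at 62.4 ± 16 and 52.5 ± 14.8 CPM (0.722), Alpl at 11 ± 6.36 and 8.82 ± 7.5 (0.904) and Sp7 at 0.182 ± 0.118 and 0.134 ± 0.0181 (0.848). Dlk1, a marker of fat cell precursors, stood at 0.807 ± 0.853 and 0.0767 ± 0.0177 CPM (−3.34 ± 1.31, 0.293), on 89 and 8 counts in all. Of 20 adipogenic transcription factors, Tcf7l1 fell, from 37.8 ± 4.89 to 22.6 ± 2.81 CPM (0.043), a call lost in 5 of the 6 fits with 1 library left out (adjusted p up to 0.156). With the replicate block 2 of these factors fell. The list as a whole did not pass (camera adjusted p = 0.135), except without untreated replicate 5 (0.0160). None of 21 mature adipocyte genes (camera adjusted p = 0.911), 23 inhibitors of adipogenesis (0.241) or 23 osteogenic transcription factors (0.171) passed edgeR's test. The members with an unadjusted p under 0.05 numbered 2, 3 and 4, DESeq2 called 0, 0 and 2, and limma-voom called 0 in each. The osteogenic factors as a list passed without untreated replicate 4 (camera adjusted p = 0.0285). With the replicate block, 2 of the mature adipocyte genes rose, Pnpla2, from 23.6 ± 5.59 to 38.1 ± 9.16 CPM (adjusted p = 0.0137), and Acsl1 (adjusted p = 0.0263), among the osteogenic factors 1 rose and 3 fell, and among the inhibitors of adipogenesis 1 rose and 1 fell. Of 29 skeletal stem cell and marrow stromal markers, 3 rose (3 up and 3 down with the replicate block) and the list did not pass (camera adjusted p = 0.753), its median being −0.12 and its mean 0.07. The stem cell antigen gene Ly6a went from 99.6 ± 36.4 to 1408 ± 355 CPM (0.00177) and Ly6c1 from 27.6 ± 17.3 to 585 ± 139.5 (0.00658). Mx1, which is also an antiviral gene, went from 1.4 ± 0.901 to 21.2 ± 10.4 (0.0114) and lost its call in 1 of the 6 fits with 1 library left out (0.0641). Tcf7l1 lost its call without untreated replicate 4, 5 or 6 or treated replicate 5 or 6. Mx1 lost its call without untreated replicate 4. Tcf7l1 (0.129) and Mx1 (0.0614) lost their calls with only the 6 libraries compared. Tcf7l1 (0.0588) lost its call with no filter beyond 1 count. It passed with the replicate block of the lines (0.00783).

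With a correlation between members estimated from the data in place of the preset 0.01, the rises of the 5 interferon and antigen presentation lists held, as did those of the chemokine, immunoregulatory, complement, cell death and glycolysis lists and the falls of the osteoblast matrix, Wnt and fibroblast matrix lists. Adjusted p was 0.000496 for the GTPases, 0.00134 for MHC class II, 0.00144 for MHC class I, 0.00781 for IFNγ signalling and 0.0111 for the antiviral genes. It was 0.0302, 0.0223, 0.0140, 0.0140 and 0.0175 for the 5 risen lists that follow, and 0.0151, 0.0179 and 0.0302 for the 3 fallen ones. With both the estimated correlation and the replicate block, the GTPases (0.00576) and the IFNγ signalling and both MHC lists (0.0110 each) passed, while the antiviral genes (0.0547) and the other 8 of these lists did not (0.0523 or more).

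**Figure D2:**
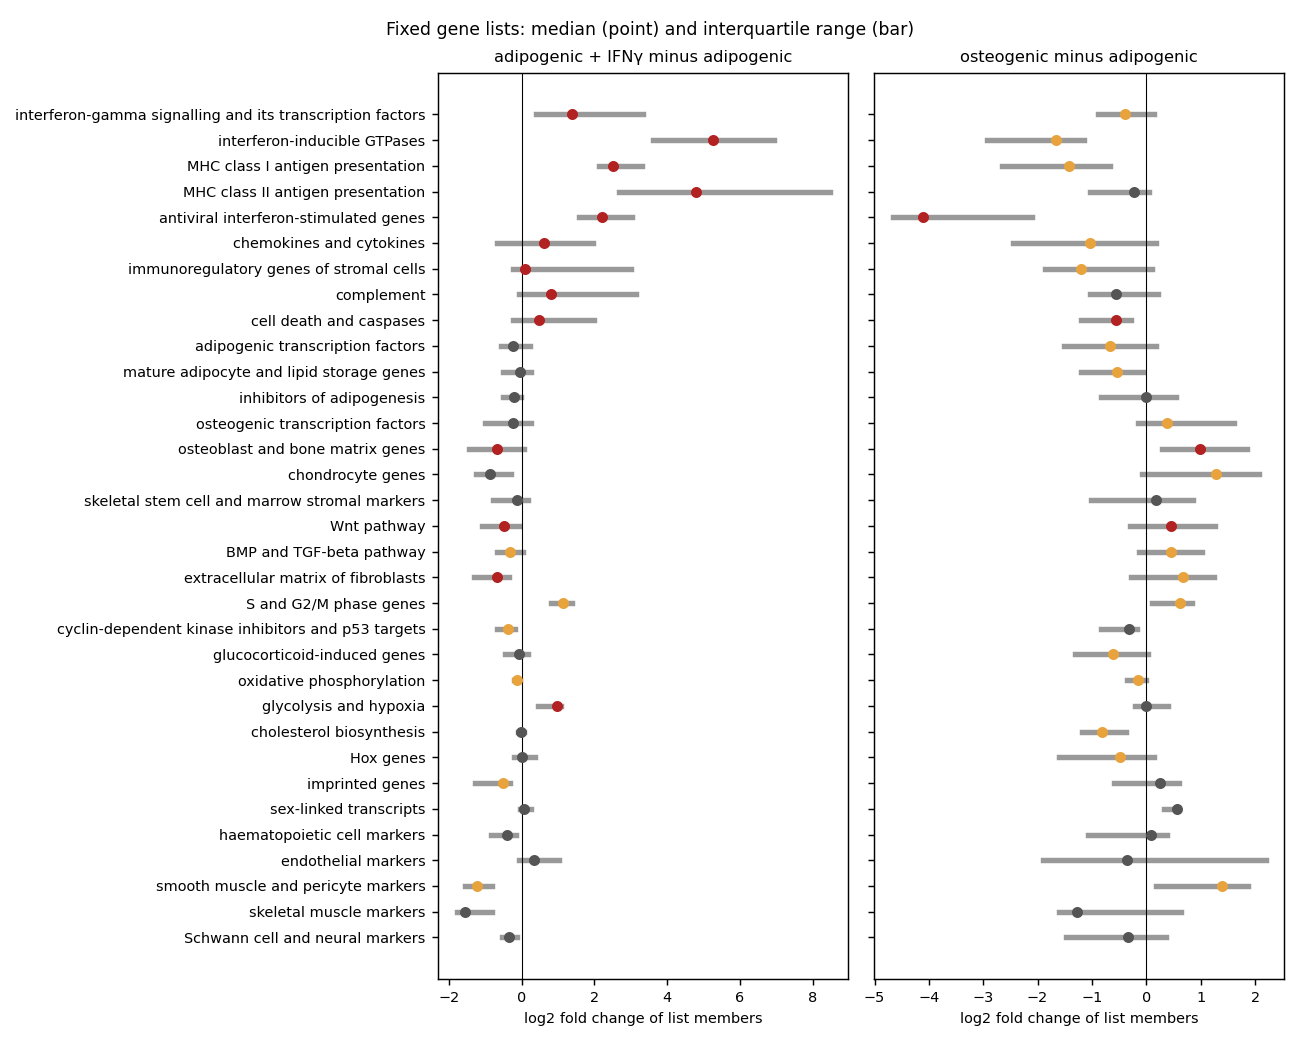
Median log2 fold change (point) and interquartile range (bar) of the tested members of each of the 33 lists, for IFNγ against untreated and for osteogenic against adipogenic progenitors. Red marks lists past a camera adjusted p of 0.05 with the preset and with the estimated correlation, orange those past it with the preset correlation only, and grey those not past it. The GTPases had the largest median with IFNγ, 5.25, and the antiviral genes the lowest in osteogenic progenitors, −4.10.

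The second comparison asked how osteogenic progenitors differed from adipogenic ones. Genes of the bone-forming lineage were higher in the osteogenic libraries, and interferon-stimulated genes were lower there. Sp7 (ENSMUSG00000060284), a transcription factor needed for bone formation, stood at 0.182 ± 0.118 CPM in adipogenic and 100.2 ± 43.2 CPM in osteogenic progenitors (log2 fold change 9.08 ± 0.56, adjusted p = 0.000589). Alpl, the gene of tissue-nonspecific alkaline phosphatase, stood at 11 ± 6.36 and 340.3 ± 70.8 CPM (4.95 ± 0.78, 0.0147), Runx2 at 62.4 ± 16 and 142 ± 9.02 (1.19 ± 0.24, 0.0328) and Col1a1 at 6899 ± 3324 and 34386 ± 7993 (2.32 ± 0.48, 0.0349). The other 4 of the 5 largest positive differences were in Tnn (ENSMUSG00000026725), a tenascin gene, at 1.3 ± 0.2 and 311 ± 186 CPM (0.00594), in the bone sialoprotein gene Ibsp (ENSMUSG00000029306), at 0.319 ± 0.0945 and 58.2 ± 71.2 (0.0279), in Insc (ENSMUSG00000048782), at 0.194 ± 0.129 and 23.5 ± 18 (0.00987), and in Tspan18 (ENSMUSG00000027217), at 0.283 ± 0.297 and 26.3 ± 13 (0.0199). The ratio of pooled counts for Sp7 was 540 (exact 95% interval 350 to 885, counting error only). With 1 library left out, the call for Ibsp was lost in 5 of 6 fits, that for Runx2 in 5, for Tspan18 in 4, for Alpl in 1 and for Col1a1 in 6, with adjusted p up to 0.104, 0.111, 0.0744, 0.0568 and 0.105. Ibsp lost its call without adipogenic replicate 4, 5 or 6 or osteogenic replicate 4 or 5. Tspan18 lost its call without adipogenic replicate 5 or osteogenic replicate 4, 5 or 6. Alpl lost its call without osteogenic replicate 4. Runx2 lost its call without adipogenic replicate 4 or 6 or osteogenic replicate 4, 5 or 6. Ibsp (0.251) and Insc (0.0502) lost their calls with limma-voom. Ibsp (0.0637) and Col1a1 (0.0508) lost their calls with only the 6 libraries compared.

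The 5 largest negative differences were in Nkx2-3 (ENSMUSG00000044220), a homeobox gene, at 34.6 ± 36.7 CPM in adipogenic and 0.141 ± 0.244 CPM in osteogenic progenitors (0.037), Oas1a (ENSMUSG00000052776), at 29 ± 20.8 and 0.391 ± 0.125 (0.00461), Mgst1 (ENSMUSG00000008540), at 27.5 ± 34.2 and 0.406 ± 0.108 (0.0315), Usp18 (ENSMUSG00000030107), at 85.1 ± 11.3 and 1.44 ± 0.462 (0.000658), and Ifit3 (ENSMUSG00000074896), at 197 ± 103 and 3.68 ± 0.404 (0.00172). Oas1a, Usp18 and Ifit3 are interferon-stimulated genes. Calls were lost with 1 library left out for Nkx2-3 in 5 of 6 fits (adjusted p up to 0.120) and for Mgst1 in 3 (0.117). In all, 780 of 15098 genes passed, 299 higher and 481 lower in osteogenic progenitors, and 517 had an absolute log2 fold change over 1. Without adipogenic replicates 4, 5 and 6 the count was 383, 475 and 228, and without the osteogenic ones 159, 231 and 204. Nkx2-3 lost its call without adipogenic replicate 4 or 6 or osteogenic replicate 4, 5 or 6. Mgst1 lost its call without osteogenic replicate 4, 5 or 6. Nkx2-3 (0.156) and Mgst1 (0.158) lost their calls with limma-voom. Nkx2-3 (0.0515) and Mgst1 (0.0511) lost their calls with only the 6 libraries compared.

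Of 33 antiviral interferon-stimulated genes, 29 were lower in osteogenic progenitors, and 32 adjusted over the list alone (camera adjusted p = 9.90e-106, with an estimated correlation adjusted p = 0.0175). Bst2, which codes for tetherin, stood at 389.9 ± 73.4 CPM in adipogenic and 18.2 ± 2.37 in osteogenic progenitors (−4.43 ± 0.20, 0.000158), Rtp4 at 50.7 ± 13.3 and 2.57 ± 0.381 (0.000279) and Ifit1 at 189 ± 34 and 4.41 ± 1.26 (0.00102). The 8 tested haematopoietic markers did not pass as a list (camera adjusted p = 0.870, median 0.09, mean −0.07), nor did any of them in edgeR's test (3 by unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom). Cd68 stood at 10.3 ± 7.27 and 3.99 ± 0.474 CPM (0.146, with DESeq2 0.0487), Cd14 at 10.2 ± 5.62 and 4.8 ± 0.779 (0.211), Lyz2 at 1.86 ± 0.657 and 1.87 ± 0.708 (0.991) and Fcer1g, named after its value was seen, at 0.294 ± 0.145 and 0.997 ± 0.743 (0.147). Of 17 IFNγ signalling genes, 4 were lower and 1, Socs3, named after its value was seen, was higher (5 and 1 over the list alone, camera adjusted p = 2.32e-05, with an estimated correlation adjusted p = 0.195). The lower genes included Stat2, at 149.6 ± 29.5 and 29.2 ± 3.04 CPM (−2.36 ± 0.18, 0.00104), Irf9 at 83.7 ± 12.1 and 19.9 ± 2.88 (0.00223) and AI451557 at 61.8 ± 13.3 and 9.29 ± 0.727 (0.00205). Irf1, Ifngr1 and Ifngr2 did not pass (adjusted p = 0.28, 0.302 and 0.506). Of 18 GTPases, 8 were lower (11 over the list alone, camera adjusted p = 4.34e-15, with an estimated correlation adjusted p = 0.0706), such as Gbp3 at 42.3 ± 11 and 5.13 ± 0.599 CPM (0.00102) and Irgm2 at 53.3 ± 16.1 and 8.92 ± 1.6 (0.00271). Of 22 MHC class I genes, 11 were lower (17 over the list alone, camera adjusted p = 1.11e-17, with an estimated correlation adjusted p = 0.0655). H2-K1 stood at 472 ± 217 and 56.3 ± 18.8 CPM (0.00991) and B2m, the light chain, at 822 ± 244 and 258 ± 33.9 (0.0111). The call for H2-K1 was lost without 1 library (adjusted p up to 0.0570) and that for B2m in 2 of 6 fits (0.0607). None of 12 MHC class II genes passed edgeR's test (3 lower by unadjusted p under 0.05, 3 by DESeq2, 0 by limma-voom), and the list did not pass (camera adjusted p = 0.154), except without adipogenic replicate 6 (0.0428) or osteogenic replicate 5 (0.0375). H2-K1 lost its call without osteogenic replicate 4. B2m lost its call without osteogenic replicate 4 or 6.

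Other immune lists were lower in part. Of 22 cell death genes, 6 were lower (10 over the list alone, camera adjusted p = 1.50e-06, with an estimated correlation adjusted p = 0.0289). Xaf1 stood at 57.3 ± 10.6 and 10 ± 4.64 CPM (0.0111) and Bid at 118 ± 18.4 and 59.8 ± 5.16 (0.0172), with calls lost in 1 and 3 of 6 fits with 1 library left out (adjusted p up to 0.0551 and 0.0702). The cell death list shares Xaf1 and Zbp1 with the antiviral list. Of 20 chemokine and cytokine genes, Cxcl14 was higher, and Cxcl10, Ccl5 and Ccl7 were lower (7 lower over the list alone, camera adjusted p = 0.0384, with an estimated correlation adjusted p = 0.231). Cxcl10 stood at 9.95 ± 2.76 and 1.26 ± 0.325 CPM (0.0133) and Cxcl14 at 0.0189 ± 0.0163 and 3.29 ± 2.41 (0.0125), the adipogenic level of Cxcl14 being 2 counts in all, for a ratio of pooled counts of 194 (exact 95% interval 53.4 to 1612, counting error only). Cxcl10 lost its call in 3 of 6 fits (up to 0.0620), Ccl5 in 6 (0.159) and Ccl7 in 5 (0.147). Cxcl12 did not pass (1216 ± 243 CPM in osteogenic progenitors, 0.324). Of 19 immunoregulatory genes, 4 were lower, Cd274, Hmox1, Lgals9 and Hgf (2 higher and 4 lower over the list alone, camera adjusted p = 0.00585, with an estimated correlation adjusted p = 0.152), Cd274 standing at 6.24 ± 1.08 and 1.31 ± 0.541 CPM (0.00659). Hmox1, Lgals9 and Hgf lost their calls in 1, 5 and 4 of 6 fits (adjusted p up to 0.0568, 0.0825 and 0.0977). Of 14 complement genes, C4b was lower (0.0458, lost in 6 of 6 fits with adjusted p up to 0.146), and the list did not pass (camera adjusted p = 0.294). Cxcl10 and Bid each lost their call without osteogenic replicate 4, 5 or 6. Ccl7 and Lgals9 each lost their call without adipogenic replicate 4 or 6 or osteogenic replicate 4, 5 or 6. Hmox1 lost its call without osteogenic replicate 4. Hgf lost its call without adipogenic replicate 6 or osteogenic replicate 4, 5 or 6. Xaf1 lost its call without osteogenic replicate 5. Ccl5 (0.075), Ccl7 (0.0622), Hgf (0.0533) and C4b (0.0744) lost their calls with limma-voom. Ccl5 (0.0613), Ccl7 (0.0936) and C4b (0.109) lost their calls with only the 6 libraries compared. Ccl5 (0.0592) and Ccl7 (0.0534) lost their calls with no filter beyond 1 count. Ccl7 (0.0505) lost its call with upper-quartile scaling. Ccl7 (0.0733) lost its call with the block over all 9 libraries.

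Lists of both lineages differed between the groups. Of 23 osteogenic transcription factors, 5 were higher, among them Sp7, Dlx5, Runx2 and Lef1, and Twist2 was lower (5 and 2 over the list alone, camera adjusted p = 0.000108, with an estimated correlation adjusted p = 0.107). Dlx5 stood at 3.23 ± 0.505 CPM in adipogenic and 36.2 ± 8.82 in osteogenic progenitors (0.0123, lost in 2 of 6 fits with 1 library left out, up to 0.0560). Of 28 osteoblast and bone matrix genes, 7 were higher and none lower (8 over the list alone, camera adjusted p = 4.25e-07, with an estimated correlation adjusted p = 0.0175). Besides Alpl, Ibsp and Col1a1 they included Omd at 8.29 ± 1.91 and 135 ± 29.1 CPM (0.00558), the parathyroid hormone receptor gene Pth1r at 0.627 ± 0.294 and 15.1 ± 8.39 (0.00752) and Col1a2 at 7210.2 ± 1769 and 24086 ± 4473 (0.0111). Of 20 adipogenic transcription factors, 3 were lower, Ppargc1a, Klf5 and Klf9, and Zfp467, a factor that favours fat over bone formation, was higher, at 4.72 ± 0.68 and 16 ± 2.83 CPM (0.00574). Klf5 stood at 16.8 ± 3.57 and 6.55 ± 1.04 CPM (0.0245). Calls for Ppargc1a, Klf5 and Klf9 were lost in 3, 6 and 5 of 6 fits (adjusted p up to 0.0777, 0.104 and 0.0915). That list was down (camera adjusted p = 0.0401), but not with an estimated correlation (0.233) nor without adipogenic replicate 4 (0.0682) or 6 (0.0522). Pparg stood at 36 ± 21.6 and 9.19 ± 4.2 CPM and did not pass edgeR's test (−1.97 ± 0.64, 0.12, with DESeq2 0.0148), nor did Cebpa (0.921) or Dlk1 (0.789). Of 21 mature adipocyte genes, Mgst1, Scd2 and Lpl were lower and Fabp5 was higher (camera adjusted p = 0.0453, with an estimated correlation adjusted p = 0.490). Fabp5, a fatty acid binding protein gene, stood at 40.8 ± 13.9 and 256 ± 76.1 CPM (0.00752) and Lpl at 143 ± 139.9 and 3.08 ± 0.812 (0.0435). Lpl lost its call in 5 and Scd2 in 6 of 6 fits (up to 0.148 and 0.124), and the list lost its own without adipogenic replicate 6 (0.199) or without any 1 of the osteogenic replicates 4, 5 and 6 (0.0759, 0.0518 and 0.0601). Of 23 inhibitors of adipogenesis, 4 were lower, Sirt1, Nr2f2, Gata3 and Twist2, with calls lost in 5, 4, 5 and 5 of 6 fits (up to 0.0833, 0.0849, 0.121 and 0.142), and the list did not pass (camera adjusted p = 0.707). Ppargc1a lost its call without adipogenic replicate 6 or osteogenic replicate 4 or 5. Klf9, Lpl and Gata3 each lost their call without adipogenic replicate 4 or 6 or osteogenic replicate 4, 5 or 6. Sirt1 and Twist2 each lost their call without adipogenic replicate 5 or 6 or osteogenic replicate 4, 5 or 6. Nr2f2 lost its call without adipogenic replicate 6 or osteogenic replicate 4, 5 or 6. Dlx5 lost its call without adipogenic replicate 6 or osteogenic replicate 4. Lpl (0.164) and Twist2 (0.0727) lost their calls with limma-voom. Lpl (0.0547), Gata3 (0.062) and Twist2 (0.0647) lost their calls with only the 6 libraries compared. Lpl (0.0577) lost its call with no filter beyond 1 count.

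Signalling and matrix lists were up by camera in osteogenic progenitors, with some members in the other direction. Of 42 Wnt genes, 3 were higher, Lrp4, Ror2 and Lef1 (4 over the list alone, camera adjusted p = 0.00042, with an estimated correlation adjusted p = 0.0340). DESeq2 called 6 of them higher and 3 lower. Lrp4 stood at 6.97 ± 2.24 and 64.9 ± 5.01 CPM (3.22 ± 0.35, 0.00387), Ror2 at 21.1 ± 3.61 and 59.2 ± 1.36 (1.49 ± 0.17, 0.00439) and Lef1 at 2.72 ± 1.6 and 18 ± 10.2 (0.0384, lost in 5 of 6 fits with 1 library left out, up to 0.123). Of 39 fibroblast matrix genes, 5 were higher, Col1a1, Col1a2, Col12a1, Ogn and, named after its value was seen, Fmod (8 higher and 1 lower over the list alone, camera adjusted p = 9.37e-05, with an estimated correlation adjusted p = 0.157). Col12a1 stood at 1112 ± 475 and 4873 ± 2465 CPM (0.0338, lost in 5 of 6 fits, up to 0.103), and Ogn lost its call as often (up to 0.0787). Of 43 BMP and TGF-β genes, Smad6 was higher, at 25 ± 11.4 and 81.5 ± 13 CPM (0.0257, lost in 4 of 6 fits, up to 0.0897). Over the list alone 5 were higher and 4 lower, and DESeq2 called 8 higher and 4 lower. This list was up (camera adjusted p = 0.00925), but not with an estimated correlation (0.437) nor without adipogenic replicate 4 (0.101). Of 13 smooth muscle markers, Smtn at 72 ± 17.9 and 184 ± 18.9 CPM (0.00928) and Myl9 at 336 ± 51 and 881 ± 303 (0.0253, lost in 4 of 6 fits, up to 0.0932) were higher (8 higher and 1 lower over the list alone, camera adjusted p = 9.37e-05, with an estimated correlation adjusted p = 0.231). The S and G2/M genes had a median of 0.61 (camera adjusted p = 0.000108, with an estimated correlation adjusted p = 0.541), and none of the 42 passed edgeR's test alone (8 higher by unadjusted p under 0.05, 4 by DESeq2, 0 by limma-voom). Lef1 lost its call without adipogenic replicate 4, 5 or 6 or osteogenic replicate 4 or 6. Smad6 lost its call without adipogenic replicate 4 or osteogenic replicate 4, 5 or 6. Ogn lost its call without adipogenic replicate 4, 5 or 6 or osteogenic replicate 4 or 5. Col12a1 lost its call without adipogenic replicate 5 or 6 or osteogenic replicate 4, 5 or 6. Myl9 lost its call without adipogenic replicate 4 or 6 or osteogenic replicate 5 or 6. Lef1 (0.0695), Smad6 (0.0526), Col12a1 (0.068) and Myl9 (0.0513) lost their calls with only the 6 libraries compared.

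Treated adipogenic and osteogenic progenitors differ in both kind and treatment, so this comparison is given in brief. Of 15098 genes, 2525 passed, 1389 higher and 1136 lower in the treated adipogenic libraries, a balance that turned to 1209 higher and 1338 lower with upper-quartile scaling. Without treated replicates 4, 5 and 6 the count was 1933, 1979 and 1448, and without the osteogenic ones 1331, 1312 and 1422. All 18 GTPases and 31 of 33 antiviral genes were higher in the treated adipogenic progenitors (camera adjusted p = 6.40e-94 and 6.41e-125), as were 19 of 22 MHC class I genes (1.03e-54), 9 of 12 MHC class II genes (1.89e-27) and 15 of 26 glycolysis genes (2.49e-06). Of 28 osteoblast matrix genes 13 were lower (9.31e-10), as were 16 of 39 fibroblast matrix genes (4.37e-10) and 13 of 42 Wnt genes (2.99e-06). With an estimated correlation these calls held (adjusted p = 0.00446 to 0.0369), except that of the glycolysis genes (0.0691).

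Both main comparisons used the same 3 untreated adipogenic libraries. Across the 15098 genes, which are not independent replicates, the log2 fold changes with IFNγ and those of osteogenic against adipogenic progenitors had a Pearson correlation of −0.129, with the same sign for 52.2% of genes. Without untreated replicate 4, 5 or 6 the correlation was 0.0532, −6.89e-05 and −0.0249. In 20 simulations of unchanged groups the shared libraries alone gave a mean correlation of 0.494 (0.477 to 0.512), or 0.372 (0.347 to 0.390) when treated and untreated libraries shared their lines. The covariance was −0.115, against simulated values of 0.144 and 0.0734, a difference of −0.259 and −0.188. The simulations gave every group the adipogenic means and the same spread, although the osteogenic libraries differed less among themselves. Tested genes nearly absent from the adipogenic libraries were thus simulated near 0 in all groups. The simulated values are therefore only a rough reference for these data. Of the genes past the threshold in both comparisons, 85 rose with IFNγ and were lower in osteogenic progenitors, where independent lists would share 9.68. Another 7 rose and were higher (6.02), 5 fell and were lower (1.18), and 7 fell and were higher (0.733). The simulated unchanged groups gave 0.05 calls per simulation on average. Part of any overlap of calls in the same direction may come from the shared libraries, which cannot be split into parts of 2 or more.

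**Figure D3:**
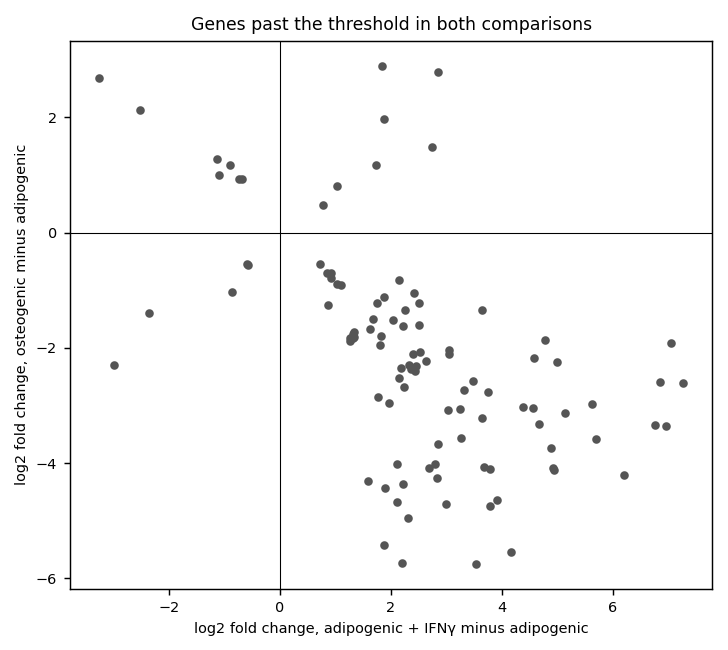
Log2 fold change with IFNγ (x axis) against log2 fold change of osteogenic over adipogenic progenitors (y axis) for the genes past an adjusted p of 0.05 in both comparisons, 1 point per gene. Most points, 85, lie at the lower right, higher with IFNγ and lower in osteogenic progenitors.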

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

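Of the tests below, only the splits of the libraries and the check on GC content and gene length were fixed before their result was seen. Among the 10 splits of the 6 libraries of a comparison, 1, the real one, gave as many changed genes in each case, 341 for IFNγ against untreated, 780 for osteogenic against adipogenic and 2525 for IFNγ-treated against osteogenic, while the highest other split gave 0. For IFNγ against untreated, the other splits that part all 3 same-numbered pairs also gave 0 at most. So few splits allow no share under 0.05. Every other split also puts libraries of both real groups together, so that real differences enter its spread. Its 0 calls therefore carry little information.

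Antiviral interferon-stimulated genes were lower in osteogenic libraries, with mean log2 CPM over the list of 5.12, 4.51 and 5.66 in untreated adipogenic and 1.91, 1.61 and 1.63 in osteogenic replicates 4, 5 and 6. Reads carried over from treated libraries are argued against, since the antiviral genes would need a median share of 19.5% where the GTPases allow 2.77%, a ratio of 7.04, and a single library by a camera adjusted p of at most 3.17e-71 with any 1 left out. Blood cells in the adipogenic libraries are argued against as the whole cause, though not as a small part, on an assumption only. It is that such cells brought all 8 haematopoietic markers, with little of them from the progenitors themselves. These markers would then be lower in osteogenic libraries by about the antiviral median on this scale, −3.55. Their mean difference was −0.100 (SD 0.970 over members, which are unlike genes) and the lowest, Coro1a, −1.25. Adipogenic and osteogenic CPM were 10.3 and 3.99 for Cd68, 10.2 and 4.80 for Cd14 and 1.86 and 1.87 for Lyz2. Those of Fcer1g were 0.294 and 0.997. Ctss (0.108 and 0.129), Laptm5 (0.133 and 0.224) and Csf1r (0.374 and 0.449) were low in both groups. That adipogenic progenitors may hold a higher interferon tone without added IFNγ stays open as a hypothesis. The gap of 2.60 between the lowest adipogenic and the highest osteogenic library cannot be told apart from differences between clones.

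S and G2/M phase genes were higher with IFNγ, with mean log2 CPM over the list of 4.32, 4.11 and 5.12 in untreated and 5.81, 5.01 and 6.05 in treated replicates 4, 5 and 6. Normalization is argued against by a list median 25.1 times the largest median shift under another scaling, and a single line by median differences of 1.57, 0.946 and 1.03 in lines 4, 5 and 6. Whether the untreated cultures alone grew more slowly, or the treated ones faster, cannot be told apart. Osteogenic libraries had means of 4.80, 5.05 and 5.40, and the lowest treated library lay −0.393 from the highest of them. A candidate explanation is an effect of IFNγ on growth, which remains a hypothesis, since culture density is not given in the sources used here.

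Chromosome 19 genes were higher in adipogenic line 4, with a median deviation of 0.385 in the untreated and 0.404 in the treated library over 452 genes. Line 5 was low on this chromosome (−0.312 and −0.303), in part as a mirror of line 4. Against line 6 alone line 4 was higher by a median of 0.344 and 0.328, while line 5 differed from line 6 by −0.124 and −0.151. GC content and gene length are argued against by an adjusted median of 0.382 in the library where it was lower. An extra copy of the chromosome in part of the cells may account for it, but the median of 0.385 lies under the 0.585 that 3 copies over 2 would give, and RNA cannot tell a gained copy from regulation. No biological explanation was tested, as line is not a group of the design.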

How the results depend on the processing

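The replicate block of the adipogenic lines was chosen after the data were seen, all other alternatives before. For IFNγ against untreated, 341 genes became 1068 with DESeq2, 178 with only the 6 libraries compared, 136 with a fold minimum of 2 and 1631 with the replicate block of the lines, and 194 to 278 with 1 library left out. For osteogenic against adipogenic, 780 became 2226 with DESeq2, 73 with the fold minimum, 1244 with a replicate block over all 9 libraries, whose osteogenic numbers pair with no other group, and 159 to 475 with 1 library left out. For IFNγ-treated against osteogenic, 2525 became 3830 with DESeq2, 545 with the fold minimum and 1312 to 1979 with 1 library left out. Left-out fits have fewer libraries from which to estimate the spread, and the fold minimum tests a stricter hypothesis. For the other changes the cause was not tested.

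The correlation of the fold changes, −0.129, was −0.229 with the stricter filter, −0.159 with the replicate block over all 9 libraries, and −0.0249 to 0.0532 with 1 untreated library left out, turning positive without replicate 4 (0.0532). Shared libraries alone make this correlation positive, and no simulation was run with 1 library left out. A positive sign there does not show that the relation turned. The cholesterol biosynthesis list, at a median of −0.03 with IFNγ, ran from −0.255 to 0.354 with 1 library left out, the highest without untreated replicate 6 (camera adjusted p = 0.0184), and the cause was not tested. Over all settings, 24 values of the counts and the correlation kept their call or stayed within 1.5 times, 5 were larger, 18 smaller, 3 moved and 1 turned. Of the list values 811 kept their call or stayed without one, 70 lost a call and 11 gained one. Another 31 without a call changed the direction given by the list test, though not always the sign of the median, and 1 turned. Of the values of named genes 3765 kept their call or stayed without one, 405 lost a call, 170 gained one and 35 without a call changed sign. Among genes and camera list tests with printed IFNγ values, the paired fit of the lines changed no call beyond those given with its value. Counts of members called over all genes and printed without that fit stayed within 1.5 times. Counts over the list alone moved more in some lists. With the paired fit, 14 Wnt genes fell in place of 3 and 3 rose in place of 0. Fallen fibroblast matrix genes went from 11 to 19, risen S and G2/M genes from 25 to 39 and risen complement genes from 4 to 7. The block over all 9 libraries ended the osteogenic calls of the chemokine list (0.105), the adipogenic transcription factors (0.0860), Ccl7 and Col11a1 and the IFNγ call of Fos. The fold minimum ended 16 of 54 calls of named genes with IFNγ and 56 of 83 in osteogenic against adipogenic progenitors. Scaling moved the median of all genes by −0.0663 at most. Depth of 27440089 to 39251602 counts limits statements on genes near 0.0764 to 0.109 CPM.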

Other observations

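Patterns by line and by chromosome in the last paragraph were looked for only after the data were seen. Among 12 chondrocyte genes, 3 were higher in osteogenic than in adipogenic progenitors (camera adjusted p = 0.00537, with an estimated correlation adjusted p = 0.105). Fgfr3, a growth factor receptor gene, stood at 3.66 ± 1.1 CPM in adipogenic and 14.5 ± 4.78 in osteogenic progenitors (0.0158), Sox6 at 0.0554 ± 0.0496 and 2.12 ± 1.55 (0.0227) and the collagen gene Col11a1 at 125 ± 46.4 and 634 ± 353 (0.034). Their calls were lost in 4, 4 and 5 of 6 fits with 1 library left out (adjusted p up to 0.0679, 0.0865 and 0.104). Of 33 tested Hox genes, which mark position along the body, 5 were lower in osteogenic progenitors, Hoxd9, Hoxd8, Hoxb7, Hoxd3 and Hoxd4 (2 higher and 8 lower over the list alone, camera adjusted p = 0.00745, with an estimated correlation adjusted p = 0.148). The last 2 were named after their values were seen. Hoxd9 stood at 4.76 ± 2.79 and 0.0101 ± 0.0174 CPM (0.0111), with 1 count in all osteogenic libraries and a ratio of pooled counts of 460.3 (exact 95% interval 82.3 to 18214), and Hoxd8 at 7.35 ± 4.75 and 0.195 ± 0.0532 (0.0145). Hoxd9, Hoxd8 and Hoxb7 lost their calls in 2, 3 and 3 of 6 fits (up to 0.0607, 0.0728 and 0.0905). Of 22 cholesterol biosynthesis genes, 4 were lower, Mvd (0.0204), Sc5d (0.0237), Insig1 (0.0351) and Sc4mol (0.0402), with 6 lower over the list alone (camera adjusted p = 1.45e-05, with an estimated correlation adjusted p = 0.454). Their calls were lost in 3, 4, 5 and 5 of 6 fits (up to 0.0831, 0.0892, 0.125 and 0.1296). Of 16 glucocorticoid-induced genes, the metallothionein gene Mt1, at 135 ± 12.8 and 32.5 ± 7.43 CPM (0.00174), and Klf9 (0.0281) were lower (camera adjusted p = 0.0218, with an estimated correlation adjusted p = 0.2005), and the list lost its call without adipogenic replicate 6 (0.0640) or osteogenic replicate 4 (0.0759). Klf9 lost its call in 5 of 6 fits (up to 0.0915). Klf9 and Insig1 each lost their call without adipogenic replicate 4 or 6 or osteogenic replicate 4, 5 or 6. Fgfr3 lost its call without adipogenic replicate 4 or 6 or osteogenic replicate 4 or 5. Sox6 lost its call without adipogenic replicate 5 or 6 or osteogenic replicate 4 or 6. Col11a1 lost its call without adipogenic replicate 4, 5 or 6 or osteogenic replicate 4 or 6. Mvd and Hoxd8 each lost their call without osteogenic replicate 4, 5 or 6. Sc5d lost its call without adipogenic replicate 5 or 6 or osteogenic replicate 4 or 5. Sc4mol lost its call without adipogenic replicate 5 or 6 or osteogenic replicate 4, 5 or 6. Hoxd9 lost its call without osteogenic replicate 4 or 6. Hoxb7 lost its call without adipogenic replicate 6 or osteogenic replicate 4 or 5. Hoxd8 (0.0652) lost its call with limma-voom. Col11a1 (0.0699), Sc5d (0.0521), Insig1 (0.0608) and Sc4mol (0.0554) lost their calls with only the 6 libraries compared. Col11a1 (0.0509) lost its call with the block over all 9 libraries.

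Of 50 oxidative phosphorylation genes, Cox8a was lower in osteogenic progenitors (0.0209, lost in 4 of 6 fits with 1 library left out, up to 0.0791). The list had a median of −0.16 (camera adjusted p = 0.0204, with an estimated correlation adjusted p = 0.595), lost without adipogenic replicate 5 (0.0534) or 6 (0.341) or osteogenic replicate 4 (0.0759). Of 26 glycolysis genes, Hk2 (0.00711) and Adm (0.0441) were lower and P4ha1 (0.0246) higher, and the list did not pass (camera adjusted p = 0.870, median −0.01, direction up). Adm and P4ha1 each lost their call in 5 of 6 fits (up to 0.121 and 0.0815). Of 10 endothelial markers, Kdr (0.0146) and Plvap were lower and Erg (0.0125) was higher, with 1 count of Erg in all adipogenic libraries and a ratio of pooled counts of 122 (exact 95% interval 21.5 to 4875). Plvap was named after its value was seen, Kdr and Erg each lost their call in 2 of 6 fits (up to 0.0680 and 0.0568), and the list did not pass (camera adjusted p = 0.481, median −0.36, mean 0.25). Of 29 skeletal stem cell and stromal markers, Mx1 was lower (0.0147, lost in 3 of 6 fits, up to 0.0740; list camera adjusted p = 0.998, median 0.17, mean −0.05). In osteogenic against adipogenic progenitors, edgeR called 0 genes of the cyclin-dependent kinase inhibitor and p53 list (camera adjusted p = 0.102), the imprinted (0.722, median 0.24, mean −0.04), sex-linked (0.254), haematopoietic (0.870, median 0.09, mean −0.07), skeletal muscle (0.676) and Schwann cell lists (0.534). Unadjusted p was under 0.05 for 8, 3, 0, 3, 2 and 4 members, DESeq2 called 3, 3, 0, 1, 0 and 3, and limma-voom 0, 1, 0, 0, 0 and 1. The kinase inhibitor list was down without adipogenic replicate 6 (0.0229) or osteogenic replicate 6 (0.0262). Mx1 lost its call without osteogenic replicate 4, 5 or 6. Cox8a lost its call without adipogenic replicate 5 or 6 or osteogenic replicate 4 or 5. P4ha1 lost its call without adipogenic replicate 5 or 6 or osteogenic replicate 4, 5 or 6. Adm lost its call without adipogenic replicate 4 or 6 or osteogenic replicate 4, 5 or 6. Erg lost its call without adipogenic replicate 6 or osteogenic replicate 4. Kdr lost its call without osteogenic replicate 5 or 6. Mx1 (0.112) lost its call with limma-voom. Adm (0.0807) lost its call with only the 6 libraries compared. Adm (0.0588) lost its call with no filter beyond 1 count.

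With IFNγ, Tubb3, a tubulin gene, was the 1 of 9 Schwann cell and neural markers to rise, from 6.85 ± 7.74 to 141 ± 39.4 CPM (0.0301, lost in 4 of 6 fits with 1 library left out, up to 0.103; list camera adjusted p = 0.753). EdgeR called 0 genes of the chondrocyte (camera adjusted p = 0.135), glucocorticoid-induced (0.689), oxidative phosphorylation (0.0313), cholesterol biosynthesis (0.863), Hox (0.779), imprinted (0.0374), sex-linked (0.771), haematopoietic (0.568), endothelial (0.241) and skeletal muscle lists (0.171). Unadjusted p was under 0.05 for 3, 2, 3, 0, 2, 3, 0, 2, 2 and 0 members, DESeq2 called 0, 2, 0, 0, 0, 1, 0, 1, 2 and 0, and limma-voom called 1 of the glucocorticoid-induced genes and 0 in the other 9 lists. With the replicate block, 1, 1, 0, 0, 1, 0, 1, 1, 2 and 0 members rose and 1, 2, 1, 0, 0, 2, 0, 0, 0 and 1 fell. The cholesterol biosynthesis list was up without untreated replicate 6 (camera adjusted p = 0.0184). The oxidative phosphorylation list was down (with an estimated correlation adjusted p = 0.645), but not without untreated replicate 6 (0.490) or treated replicate 4 (0.221) or 5 (0.0668). The imprinted list was down (with an estimated correlation adjusted p = 0.229), but not with the replicate block (0.0562) nor without untreated (0.0922) or treated replicate 6 (0.0944). Tubb3 lost its call without untreated replicate 5 or treated replicate 4, 5 or 6. Tubb3 (0.121) lost its call with only the 6 libraries compared.

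Some genes were near 0 in both libraries of 1 adipogenic line. In line 4, Ddx3y, a Y-linked gene, stood at 0.113 and 0.414 CPM without and with IFNγ, against 46.5 to 74.4 CPM in the other lines, the DNA repair gene Mgmt at 0.394 and 0.0296 against 21.4 to 44.8, and the imprinted gene Snrpn at 0 and 0.118 against 7.16 to 18.3. Sirpa and Zfp677 were the other 2 of the 5 such genes of line 4. The 4 Y genes with a mean of at least 1 CPM were not low as a set in line 4. Their median deviations there were 0.517 without and 0.396 with IFNγ, with 75% above 0. In line 6 these medians were −1.02 and −0.741, with 25% above 0. In line 5 Myo5b stood at 0.228 and 0.0846 against 8.86 to 17.0 CPM, and in line 6 the necroptosis kinase gene Ripk3 at 0.1996 and 0.114 against 11.6 to 21.7. Autosome medians over 0.25 in size in at least 1 library were also seen elsewhere, partly as a mirror of the other libraries of the group. In untreated and treated libraries they were −0.254 and −0.226 on chromosome 10 in line 4, −0.285 and −0.259 on chromosome 14 in line 4, 0.313 and 0.255 on chromosome 14 in line 5, and −0.312 and −0.303 on chromosome 19 in line 5. Osteogenic replicate 6 had 0.275 on chromosome 9, osteogenic replicate 5 had 0.275 on chromosome 18 and osteogenic replicate 4 had −0.271 on chromosome 14.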
